A study of Mus musculus with 2 samples.

How the data were processed

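NRF1, nuclear respiratory factor 1, is a transcription factor that binds GC-rich promoter DNA and is known for its part in the expression of nuclear genes for mitochondrial proteins. The samples were 2 chromatin immunoprecipitation libraries, made with an antibody to NRF1, from CH12.LX, a mouse B-cell lymphoma line labelled female. The libraries are biological replicates per the labels, numbered 1 and 2, and form 1 group. The design therefore holds no comparison between groups, and a control library, named only as an input in the notes deposited with the samples, was not analysed here.

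The peak lists were made by the authors and were used as deposited. Per the text files deposited with the samples, a relaxed list of peaks and background was called on mm10 for each replicate and for the pooled replicates, each with a control, and a conservative and an optimal set were then selected by irreproducible discovery rate, a measure of how far peak ranks recur between replicates. Those notes also name a peak set on mm9 made from both replicates, with no control among its inputs. The aligner, the peak caller, its thresholds and the number of reads are not given in the sources used here, so depth is unknown and no depth-based interval was computed. Each relaxed list holds 300000 peaks. Per the file format of the deposited lists, each peak has a signal value from the authors' caller, whose scaling is not given in the sources used here, and it served only to rank, describe and split peaks within a list. The deposited score columns (the rank score of the selected sets, and a significance column of the mm10 lists that goes below 0) described the sets and entered no test, and the −log10 significance column deposited for the mm9 set was not used further. Signal values on mm9 and mm10 are on different scales and were never compared with each other.

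Peaks on chromosomes 1 to 19 and X were analysed. The genome sequence at hand was NCBIM37 (mm9) with GENCODE vM1, and the mm10 gene coordinates came from the RefSeq table of GRCm38.p6, which has no strand. No coordinate was converted between builds. Of 21631 protein-coding RefSeq genes on these chromosomes, 18380 took their strand from GENCODE by symbol and 2157 by synonym, and 1094 without a match were left out, leaving 20537 genes with 1 transcription start site (TSS) each. As a check of the strand, 613 genes had a peak summit within 1000 bp of the 3' end, against 7729 within 1000 bp of the TSS. A promoter peak has its summit within 1000 bp of a TSS, and a gene with such a peak is called occupied. All sequence results used the mm9 set with NCBIM37 and GENCODE transcripts. This departs from the plan, which assumed an mm10 genome for the optimal set. The genome file holds 0 lower-case bases on these chromosomes, so the planned comparison of repeats was not run. CpG-rich promoters (GC above 0.5 and CpG observed/expected above 0.6 in the 1000 bp around a TSS) and promoters with the NRF1 consensus GCGCAYGCGC were found on mm9 and passed to mm10 genes by symbol only.

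Motifs were sought on both strands within 50 bp of each mm9 summit and compared with windows centred 500 bp to either side by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the 16 consensus motifs or over all 8-mers tested. Differences of medians and correlations were tested by two-sided permutation with 100000 resamples, whose smallest possible p is 1e-05. Shares of promoter peaks and of peaks shared by replicates were compared with 100 random placements on the same chromosomes, within the span of the pooled relaxed list on mm10. The 21 gene lists, the motifs, the tests and the rule for named genes were fixed before the data were examined. List occupancy was tested by two-sided Fisher's exact tests against all other protein-coding genes, adjusted over the 21 lists. Fisher p-values below 1e-300 are written as 1e-300. Shares carry 95% Wilson intervals. Peaks and genes are not independent replicates, and intervals and p-values cover counting error only. Values given as mean ± SD are over the 2 replicates, taken from the N = 17547 peaks of highest signal in each relaxed list for occupancy, or from the overlapping relaxed peak for signal.

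The named genes were the 12 protein-coding genes with the highest-signal promoter peaks among peaks seen in both replicates, the 3 strongest occupied members and the first 2 unoccupied members in alphabetical order of each list with raised occupancy, the strongest occupied member of each other list, and 9 genes fixed in advance (Nrf1, Tfam, Tfb1m, Tfb2m, Cycs, Cox5b, Alas1, Gabpa and Nfe2l1), with the 5 strongest distal peaks. Other genes named in the text were chosen after their values were seen, and 1 gene that the rule names is not reported here. The alternatives were the conservative set, the 8773 optimal peaks of higher signal, each replicate alone, promoters of 500 or 2000 bp, other motif definitions, windows and backgrounds, and only CpG-rich genes for the lists. The mm9 set for gene results, the removal of chromosome 11, the higher-signal peaks with CpG-rich genes only, CpG-rich genes for divergent promoters and chromosome X, and the recount of the named genes were added after seeing the data. The analysis ran in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The steps were tested on simulated data. For the motif search, 100% of 200 planted motifs were recovered with 0% of the other 1800 windows called, and all 17 8-mers called among 32771 shared at least 7 bases in a row with the planted motif. All simulated windows had the same even base composition, so this does not show how specific the tests are where summits and flanks differ in composition. For the gene lists, 90% of 10 lists with raised occupancy and 0% of 200 other lists were called. For the permutation test, 97% of 200 pairs shifted by 1 SD and 3.5% of 200 unshifted pairs were called.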

Results

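NRF1 binding was mapped by chromatin immunoprecipitation and sequencing in CH12.LX, a mouse line derived from a B-cell lymphoma, in 2 biological replicates. The question of the design is where NRF1 sits in this genome. The optimal set held 17554 peaks with a median width of 344 bp that covered 5.60 Mb, the conservative set 15941 peaks, and the mm9 set 11217 peaks with a median width of 376 bp. Signal in the optimal set ran from 4.71 to 703 with a median of 38.1, and 11856 of its peaks carried the highest rank score of 1000.

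The genes with the strongest promoter peaks, taken among peaks seen in both replicates, had signals from 677 to 703, and some distal peaks were as strong. The highest signal of all, 703, lay at Dhx37, which encodes an RNA helicase of ribosome assembly (chromosome 5, 125433918 to 125434307, mm10), with the summit 26 bp inside the gene and 354 ± 10.7 in the replicates (SD, n = 2). Pop7, a subunit of ribonuclease P, followed at 698 (chromosome 5, 137502224 to 137502691, summit at -27 bp). Rps6ka5, a protein kinase gene, reached 689 (chromosome 12, 100725080 to 100725533, summit at -7 bp), Fnbp4 687 (chromosome 2, 90745231 to 90745625, summit at -7 bp) and Sf1, a splicing factor gene, 685 (chromosome 19, 6363291 to 6363696, summit at -193 bp). The other strongest promoters were those of Izumo4 (683), the condensin subunit genes Ncapg2 (682) and Smc4 (678), the actin-capping gene Capza2 (679), the zinc finger gene Zfp82 (677), Mvd of the mevalonate pathway (677) and Ift172 of intraflagellar transport (677). The conservative set had a peak at all 12 genes too.

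Of the 17547 highest-signal peaks of replicate 1, 12678 (72.3%) overlapped one of the 17547 highest of replicate 2 by at least 1 bp, against a mean of 0.545% and a highest value of 0.690% in 100 random placements. All 4386 strongest optimal peaks overlapped a top peak of each replicate (100%), and 15.5% of the 4387 weakest did. Across 17181 optimal peaks with a peak in both relaxed lists, signal correlated between replicates with a Spearman rho of 0.849 and a Pearson r of 0.921 on log2 signal (permutation p = 1e-05 for each, the smallest the resamples can give). The rho was 0.931 over the stronger optimal peaks (8767 with a peak in both) and 0.143 over the weaker ones (8414 with a peak in both). The optimal set was selected by irreproducible discovery rate, per the text files deposited with the samples, so these correlations describe selected peaks and do not test how far the replicates match. Peaks within 1 genome are not independent of each other.

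Promoters took a large share of the peaks. Of 17547 optimal peaks, 8217 (46.8%, 95% Wilson interval 46.1 to 47.6) had their summit within 1000 bp of a TSS, where 100 random placements gave a mean of 1.67% and at most 1.89%. The share was 68.9% among the 4386 strongest peaks and 27.9% among the 4387 weakest. Promoter peaks had a median signal of 61.4 (quartiles 29.0 and 336) and distal peaks one of 27.7 (19 and 60.2), a difference of 33.7 (permutation p = 1e-05, the smallest the resamples can give). In all, 7729 of 20537 protein-coding genes were occupied (37.6%), 7972 by the top peaks of replicate 1 and 7704 by those of replicate 2, with 7113 genes in both. Occupancy followed CpG content: 6426 of 10417 genes with a CpG-rich promoter were occupied (61.7%) and 1262 of 9869 other genes (12.8%; odds ratio 11, Fisher's exact p at the smallest value written, 1e-300).

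The NRF1 consensus GCGCAYGCGC lay under 987 of 11216 mm9 summits (8.80%, interval 8.29 to 9.34) and in 33 of 22432 flanking windows (0.147%), a 59.8-fold difference (odds ratio 65.5, Fisher's exact p at the smallest value written, 1e-300). Among 1123 peaks with a consensus site within 500 bp of the summit, the nearest site was centred within 20 bp of it in 840 (74.8%), at a median distance of 12.0 bp. Dhx37 carried GCGCATGCGC in its 5' UTR at 1 bp from the TSS (chromosome 5, 125914486 to 125914495, mm9), and Capza2 carried 3 sites, the nearest at 11 bp (GCGCGTGCGC on the plus strand, chromosome 6, 17586990 to 17586999, 5' UTR). In Uqcrc1, a subunit gene of respiratory complex III, GCGCATGCGC lay at -29 bp (chromosome 9, 108838691 to 108838700, 5' UTR). The promoter of Alas1, the first enzyme of heme synthesis, held GCGCATGCGC at -64 bp (chromosome 9, 106150247 to 106150256) and GCGCACGCGC at -93 bp. An mm9 peak covered each of these sites.

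**Figure D1:**
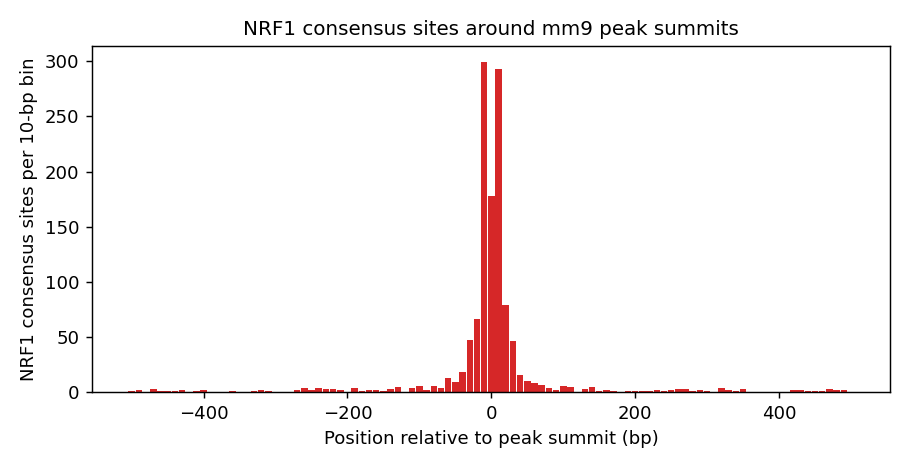
Number of NRF1 consensus sites per 10-bp bin (y axis) by position relative to the mm9 peak summit in bp (x axis), all mm9 peaks combined. The sites crowd around the summit: 840 of 1123 peaks with a site have the nearest one centred within 20 bp.

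Peaks with the consensus were far stronger than peaks without it. Their median mm9 signal was 1978 (quartiles 647 and 4351) over 987 peaks, against 87.5 (48.7 and 364) over 10229 peaks without it (permutation p = 1e-05, the smallest the resamples can give). When the mm9 peaks were divided by signal into 10 classes of equal size, 36.2% of the 1122 strongest peaks held the exact consensus (interval 33.4 to 39.0) and 0.357% of the 1121 weakest did (0.139 to 0.914). With up to 1 mismatch to GCGCATGCGC allowed, the shares were 86.2% and 3.75%, and 25.6% of all peaks held such a site. The promoter share rose from 44.3% in the weakest class to 90.3% in the strongest.

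**Figure D2:**
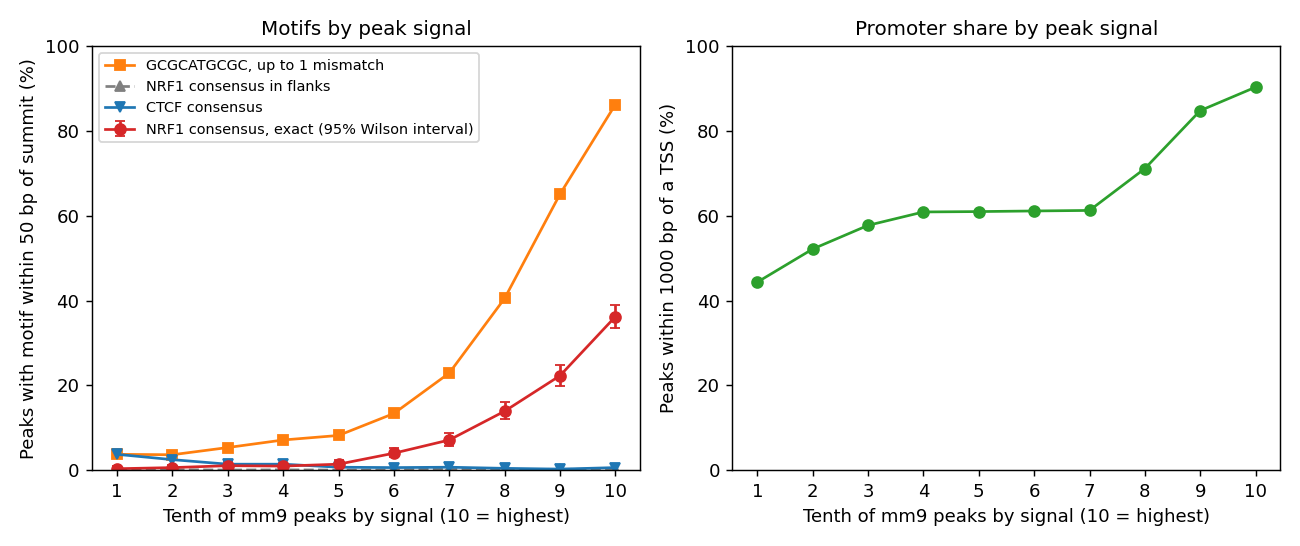
Left, the percentage of mm9 peaks with a motif within 50 bp of the summit (y axis) in 10 classes of signal (x axis, 10 the highest), for the exact NRF1 consensus with 95% Wilson intervals, the site with up to 1 mismatch, the NRF1 consensus in the flanks and the CTCF consensus. Right, the percentage of peaks within 1000 bp of a TSS in the same classes. The exact NRF1 consensus rises from 0.357% to 36.2%, while the CTCF consensus is at 3.75% in the weakest class and 0.624% in the strongest.

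Among 32895 8-mers tested without a motif given, parts of the NRF1 consensus YGCGCAYGCGCR were at the smallest p written, 1e-300, by Fisher's exact test. Of these, GCATGCGC lay under 12.3% of summits and in 0.285% of flanks, and CGCATGCG under 6.78% and in 0.0624%. Tied with them at that p were 8-mers outside the consensus as written, among them GCCTGCGC (11.8% of summits and 0.535% of flanks) and GCGCGCGC (8.21% and 0.562%). GCCTGCGC differs from GCATGCGC by 1 base, so the exact consensus may leave out a close variant. What binds these 8-mers was not tested, so neither another factor nor base composition was ruled out for them. Sites of other promoter factors were also more frequent at summits than in flanks: YY1 (2.51% against 0.165%), the ETS family (5.31% against 0.633%), CREB (1.44% against 0.134%), ZNF143 (0.651% against 0.0446%), SP/KLF factors (5.70% against 1.5%), NFY (7.23% against 2.94%) and E2F (3.49% against 0.860%), with adjusted Fisher's exact p-values between 1.93e-157 and 8.49e-25. CTCF, the insulator protein, had its site under 1.25% of summits and in 0.0802% of flanks (adjusted exact p = 2.65e-47). The antioxidant response element bound by NFE2L1, a different protein that shares the alias NRF1, lay under 3.01% of summits and in 1.71% of flanks (adjusted exact p = 5.62e-14), a 1.76-fold difference beside the 59.8-fold of the NRF1 site. Of the B-cell factors, EBF sites did not differ (0.366% against 0.361%, adjusted exact p = 1.0), RUNX sites were rarer at summits (0.633% against 0.856%, adjusted exact p = 0.0321), and PU.1 sites were more frequent (1.12% against 0.620%, adjusted exact p = 1.91e-06). Past the adjusted threshold, 5294 8-mers were more frequent at summits and 9570 less frequent, so summits and flanks differ widely in sequence. Flanks were not matched to summits in base composition. Only the NRF1 motif was also set against dinucleotide shuffles, so composition was not ruled out for the other motifs.

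Most NRF1 consensus sites in the genome were not under a peak, and promoter sites were. Of 5637 consensus sites on the mm9 chromosomes, 1156 lay in an mm9 peak (20.5%, interval 19.5 to 21.6). The share was 77.1% of 1208 promoter sites, 4.72% of 2076 sites in gene bodies and 5.40% of 2353 intergenic sites (promoter against the rest, odds ratio 62.8, Fisher's exact p at the smallest value written, 1e-300). The mm9 set had no peak over the sites of Pop7, Timm29, Mcm4 and Prkdc, whose promoters carried optimal signals of 698, 603, 628 and 628, so these counted as unbound and the shares hold for the mm9 set only. Sites in CpG-rich surroundings were bound in 54.0% of cases and those in CpG-poor surroundings in 4.46%. Each feature went with a higher bound share within the other: 82.6% of CpG-rich promoter sites and 27.9% of CpG-poor promoter sites were bound, and outside promoters CpG-rich sites were bound in 10.5% (gene bodies) and 13.3% (intergenic) of cases against 3.66% and 3.71% for CpG-poor ones (odds ratio 3.58, adjusted exact p = 8.97e-17). The palindrome GCGCATGCGC and the other form did not differ at promoters (78.2% of 403 against 76.5% of 805, adjusted exact p = 0.599) and differed elsewhere (odds ratio 2.34 for the palindrome, adjusted exact p = 2.64e-09).

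**Figure D3:**
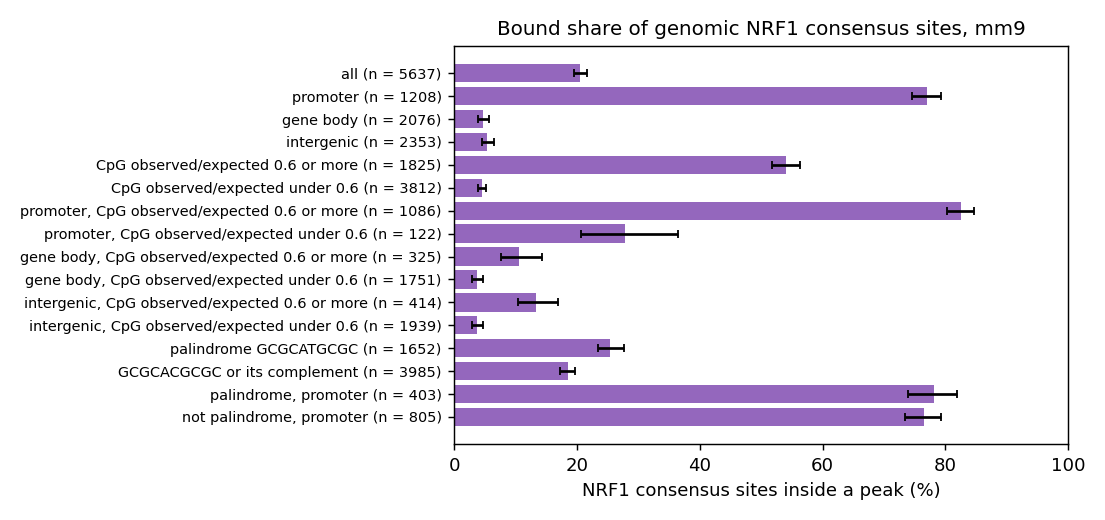
Percentage of genomic NRF1 consensus sites that lie inside an mm9 peak (x axis) by class of site (y axis, with the number of sites), with 95% Wilson intervals. Promoter sites in CpG-rich surroundings stand at 82.6%, sites outside promoters at 13.3% or less.

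Genes for mitochondrial proteins were occupied more often than other genes. Of the genes for oxidative phosphorylation subunits, 67 of 86 were occupied (77.9%, interval 68.1 to 85.4, against 37.5% of other genes, odds ratio 5.89, adjusted Fisher's exact p = 1.57e-13), led by Atp5c1 of ATP synthase (661), Uqcrc1 (659) and Ndufa8 of complex I (657). Cox5b of complex IV (546) and Cycs, cytochrome c (409), were occupied, and Atp5g3 and Cox4i2 were the first unoccupied members, though Atp5g3 had a peak of 517 at 1155 bp from the TSS used. Of mitochondrial ribosomal protein genes, 66 of 78 were occupied (84.6%, adjusted exact p = 1.5e-16), with Mrpl9 (629), Mrpl17 (622) and Mrpl54 (611) strongest and Mrpl15 and Mrpl16 without a peak. Occupied members of these lists also carried strong peaks more often than other occupied genes, 89.6% and 90.9% in the 8773 higher-signal peaks against 73.2% of the rest for each list (adjusted exact p = 0.0113 and 0.00618). Mitochondrial protein import (20 of 25, adjusted exact p = 3.94e-05, led by Timm8b at 609, Timm29 at 603 and Timm13 at 515, with Timm10 and Timm10b unoccupied) and mitochondrial aminoacyl-tRNA synthetases (15 of 17, adjusted exact p = 3.94e-05, led by Vars2 at 629, Yars2 at 578 and Mars2 at 538, with Aars2 and Tars2 unoccupied) were raised as well. The replicate mean occupancy was 77.9% ± 0 (SD, n = 2) for oxidative phosphorylation and 87.8% ± 0.907 for mitochondrial ribosomal proteins.

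Genes that act on mitochondrial DNA gave a mixed picture. Polrmt, the mitochondrial RNA polymerase, carried a peak of 642 with GCGCACGCGC in the 5' UTR at 3 bp (chromosome 10, 79209317 to 79209326, mm9) and again at -1 bp (79209323 to 79209332), both under the mm9 peak. Polrmt held 2 more sites in coding exons (79201948 to 79201957 and 79202058 to 79202067), neither under a peak. Tfb2m had a peak of 276 and Tfb1m one of 45.8, while Tfam, the mitochondrial DNA packaging factor, had its nearest optimal summit 46958 bp from the TSS. Together 11 of 18 genes were occupied (61.1%, interval 38.6 to 79.7, adjusted exact p = 0.0591), which missed the threshold, though 14 were by replicate 1 alone (77.8%, adjusted exact p = 0.00128) and 12 by replicate 2 alone (66.7%, adjusted exact p = 0.0155). The list also passed in the conservative set (adjusted exact p = 0.003), the mm9 set (0.00239), with promoters of 2000 bp (0.03) and without chromosome 11 (0.0481). It missed with promoters of 500 bp (0.0891) and with the higher-signal peaks (0.0658). Among CpG-rich genes its share was below that of other genes (60%, and 46.7% with the higher-signal peaks). Heme synthesis enzymes stood at 6 of 8 (75%, adjusted exact p = 0.0658), with Alas1 at 621. The list's adjusted exact p ran from 0.00431 in the mm9 set, and 0.00693 with 7 genes by replicate 2 alone, to 0.75 with the higher-signal peaks and CpG-rich genes only. NRF1 occupied its own promoter (514, summit 126 bp inside the gene). On the list of the NRF1 gene and mitochondrial biogenesis regulators, 11 of 13 genes were occupied (adjusted exact p = 0.000941). Among them were Esrra (627), Gabpa (402) and Nfe2l1 (103), with Gabpb1 and Ppargc1b unoccupied. The list is broad: it also counts Nfe2l1, whose protein only shares the alias NRF1, and the promoter factors Sp1 and Yy1.

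Genes of translation, protein breakdown, replication, repair and splicing were also occupied more often than other genes. The counts were 67 of 82 cytosolic ribosomal protein genes (adjusted exact p = 2.26e-15, Rpl10 at 564 and Rps12 at 554 strongest, Rpl10l and Rpl17 unoccupied). Occupied too were 16 of 18 cytosolic aminoacyl-tRNA synthetases (adjusted exact p = 1.96e-05, Kars at 636, Gars at 542 and Tars at 539, Aars and Eprs unoccupied) and 31 of 39 proteasome subunits (adjusted exact p = 3.2e-07, Psmc4 at 630, Psma2 at 510 and Psmd2 at 495, Psma6 and Psma8 unoccupied). Further counts were 37 of 50 DNA replication factors (adjusted exact p = 4.89e-07, Pola2 at 659, Mcm4 at 628 and Wdhd1 at 623, Gins1 and Gins4 unoccupied), 42 of 47 DNA repair factors (adjusted exact p = 9.19e-13, Prkdc at 628, Lig4 at 622 and Atm at 619, Atrip and Ercc1 unoccupied) and 41 of 46 core spliceosome proteins (adjusted exact p = 1.83e-12, Lsm7 at 662, Prpf3 at 634 and Prpf39 at 621, Prpf18 and Sf3b6 unoccupied). Mcm4 and Prkdc are transcribed away from each other and share 1 peak (chromosome 16, 15637688 to 15638056, mm10). Of occupied cytosolic ribosomal protein genes, 71.6% carried a higher-signal peak against 73.4% of other occupied genes (adjusted exact p = 0.928). Against genes with a CpG-rich promoter only, the calls ended for the cytosolic synthetases (adjusted exact p = 0.0887) and the biogenesis regulators (0.265), and the other 9 raised lists passed. With the higher-signal peaks and CpG-rich genes only, 3 lists passed, oxidative phosphorylation (adjusted exact p = 2.34e-06), mitochondrial ribosomal proteins (3.76e-07) and the spliceosome (0.00333). The other raised lists had adjusted exact p-values from 0.0563 (mitochondrial synthetases and DNA repair) to 0.841 (cytosolic synthetases). The regulators also missed the threshold in the mm9 set (61.5%, adjusted exact p = 0.0791). Genes are called unoccupied here by the optimal set and 1 TSS per gene. In the mm9 set with all GENCODE start sites, promoter peaks stood at 9 of those named so: Atp5g3 (mm9 signal 2011), Gabpb1 (1488), Eprs (229), Aars2 (185), Tars2 (80.5), Aars (71.2), Timm10 (57.6), Psma6 (50.8) and Gins4 (39.98).

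Genes of other tissues were seldom occupied. Olfactory receptors had 3 of 1099 genes occupied (0.273%, interval 0.0929 to 0.799, adjusted exact p = 7.71e-225), and muscle genes 0 of 26 (interval up to 12.9, adjusted exact p = 1.21e-05). Germline genes had 0 of 36 occupied (interval up to 9.64, adjusted exact p = 1.92e-07), hepatocyte genes 1 of 25 (Apoa2, 509, summit 913 bp inside the gene, adjusted exact p = 0.000318), T cell and myeloid genes 1 of 29 (Cd5, 15.3, adjusted exact p = 3.94e-05) and synapse genes 4 of 29 (Stx1a strongest at 596, adjusted exact p = 0.00837). Against genes with a CpG-rich promoter only, which leaves 3 T cell and myeloid and 2 muscle genes, those calls ended (adjusted exact p = 0.0887 and 0.186). The calls held there for germline genes (0 of 22 against 61.8% of other such genes, adjusted exact p = 1.25e-08) and synapse genes (2 of 10, adjusted exact p = 0.0216). Olfactory receptors and hepatocyte genes had 0 members with a CpG-rich promoter, so that comparison could not be made for them. Genes without a CpG-rich promoter were occupied in 12.8% of cases, and neither list was tested against these alone. That share lies within the interval of the hepatocyte list (0.710 to 19.5) and above that of the olfactory receptors. The synapse call ended without chromosome 11 (17.4%, adjusted exact p = 0.0847). The olfactory receptor gene Olfr1491 held a peak of 71.0 over GCGCATGCGC in its coding exon (chromosome 19, 13780011 to 13780020, mm9). B cell identity genes, the lineage of this line, did not pass the test against other genes (16 of 40, 40%, interval 26.3 to 55.4, adjusted exact p = 0.747). With the higher-signal peaks they were occupied less often (12.5% against 27.6%, adjusted exact p = 0.0407), and the share was also below that of other genes in the conservative set (27.5%, adjusted exact p = 0.323) and the mm9 set (25%, adjusted exact p = 0.245). Their occupied members carried weak peaks: 31.3% were in the 8773 higher-signal peaks against 73.4% of other occupied genes (adjusted exact p = 0.00618), with Tnfrsf13b (540) the strongest and Pax5 at 21.6 and Ebf1 at 35.7. The share was 45% by replicate 1 alone and 27.5% by replicate 2 alone. Replication-dependent histone genes did not pass either (28 of 57, adjusted exact p = 0.0802), with H4c8 strongest at 402. That summit lay 696 bp downstream of the TSS, beyond the end of the gene, and the nearest summit was a peak of 59.9 at 677 bp. The peak may therefore belong to another site. Their call depended on the setting, with a raised share for promoters of 2000 bp (56.1%, adjusted exact p = 0.0163) and a lowered one in the mm9 set (12.7%, adjusted exact p = 0.000441). Of the occupied histone genes, 46.4% carried a higher-signal peak against 73.4% of other occupied genes (adjusted exact p = 0.0113).

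**Figure D4:**
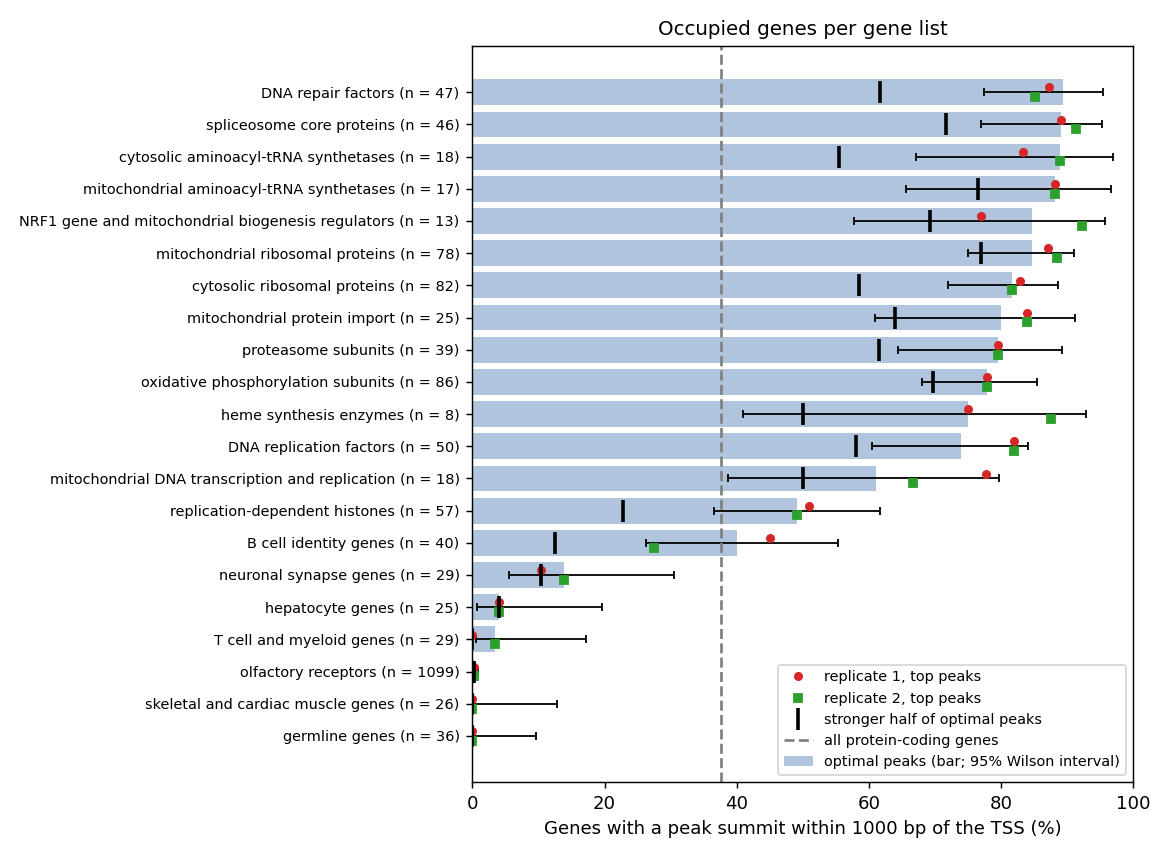
Percentage of genes with a peak summit within 1000 bp of the TSS (x axis) for the 21 gene lists (y axis, with the number of genes). Bars are the optimal set with 95% Wilson intervals, circles and squares the top peaks of replicates 1 and 2, vertical ticks the 8773 optimal peaks of higher signal, and the dashed line all protein-coding genes at 37.6%.

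Divergent gene pairs were occupied more often than other genes. Of 1428 genes whose TSS lies within 1000 bp of a TSS on the other strand, head to head, 1161 were occupied (81.3%, interval 79.2 to 83.2) against 34.4% of other genes (odds ratio 8.30, Fisher's exact p = 6.09e-270). Such pairs can share 1 peak, as Mcm4 and Prkdc do, and so count it for both genes. Within CpG-rich promoters the odds ratio was 4.28 (85.8% against 58.6%, Fisher's exact p = 2.3e-82).

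Genes on chromosome X were occupied less often than those on autosomes. Of 909 genes on X, 175 were occupied (19.3%, interval 16.8 to 21.9) against 38.5% on the autosomes (odds ratio 0.381, Fisher's exact p = 1.83e-34), and Rpl10, at 564, was the named gene on X. Among CpG-rich promoters, 122 of 263 X genes were occupied (46.4%) against 62.1% on autosomes (odds ratio 0.528, p = 4.42e-07).

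The 5 strongest distal peaks had signals from 677 to 689. They lay within the gene bounds of Maml3 (chromosome 3, 51796391 to 51796757, signal 689), Cnot8 (chromosome 11, 58103710 to 58104127, 680), Arid1b (chromosome 17, 5295698 to 5296035, 679), Lmtk2 (chromosome 5, 144181314 to 144181679, 677) and Nbeal1 (chromosome 1, 60180239 to 60180594, 677, 1685 bp from its TSS), all on mm10 and in both replicates. Of 9330 distal optimal peaks, 5205 (55.8%) lay inside a protein-coding gene. With 1 TSS per gene, an alternative promoter counts as distal here.

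The mm9 and mm10 sets come from the same libraries and shared most of their occupied genes. By gene symbol, 6223 of 7076 genes occupied in the mm9 set were occupied in the optimal set (87.9%), and 80.9% of the optimal genes with an mm9 TSS were occupied in the mm9 set. The mm9 set had no promoter peak at 151 of the 1922 genes with the strongest optimal peaks, among them Pop7, Izumo4, Mcm4 and Prkdc. Across 20 chromosomes, peaks per chromosome correlated with a Pearson r of 0.993 and a Spearman rho of 0.985 (permutation p = 1e-05 for each, the smallest the resamples can give), and r was 0.987 without chromosomes 11 and X. With the same libraries behind both sets, a high value tests little.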

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

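The rules for an outlying sample and for a difference between groups need more samples or groups than these, so the values here were picked as signal in lists that the comparisons above did not use. The tests of 5-Mb bins were written before their values were seen, after the totals per chromosome were known, and the test of gene occupancy on chromosome 11 and the bins of chromosome 16 were chosen after the result was seen.

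Pooled relaxed peaks outside the optimal peaks were dense on chromosome 11, at 268 per Mb against a median of 103 over 20 chromosomes, with 222 in replicate 1 and 238 in replicate 2. Chromosome 16 stood at 183 and chromosome X at 12.1, and genes on chromosome 11 were also occupied by optimal peaks more often than others (48.9% against 36.7%, odds ratio 1.65, Fisher's exact p = 3.45e-21). Gene density is argued against as the whole cause, since bins of chromosome 11 held a median of 2.09 times the peaks of autosomal bins with a like number of genes (quartiles 1.74 and 2.27, 22 bins), beside 1.89 for chromosome 16 (1.43 and 2.30, 18 bins). All 23 bins of chromosome 11, 100%, lay above the median bin of the other autosomes (72.2% of 18 bins for chromosome 16), which is what extra copies of chromosome 11 in this line would give, and such copies may explain the density. Dense bins were not confined to chromosomes 11 and 16. On chromosome 3, each bin from 130000001 to 155000000 held 1100 to 1673 peaks, with 474 in the bin before. The median bin held 492.5 peaks on chromosome 3 and 1370 on chromosome 11. These bins of chromosome 3 were picked after their values were seen. Copy number itself was not measured here, a chromosome-wide difference in the control stays open, and no explanation beyond gene density and extra copies was tested.

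Of the conservative peaks, 2173 overlapped no optimal peak, with a median signal of 18.0 and a highest of 130, and 28.1% had their summit at a promoter. The promoter share of the 281312 pooled relaxed peaks outside the optimal set was 4.22% (interval 4.14 to 4.29), above the 1.67% that was the highest of 100 random placements.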

How the results depend on the processing

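For the 14 results and counts that answer a comparison, 79 alternative values stayed on the same side of the threshold in the same direction, or within 1.5 times the main count, and 3 did not. The number of lists with lower occupancy, 6 in the main setting, was 2 among CpG-rich genes (germline and synapse genes), where most members of the other lists drop out. It was 1 (germline genes) with the higher-signal peaks and CpG-rich genes only. In that last setting the lists with raised occupancy were 3, against 11 in the main setting and 9 to 14 in the others. Of the other results, the promoter share ranged from 40.1% to 63.9%, the motif share from 5.02% to 25.6%, the odds ratio of divergent pairs from 4.28 to 8.99 and that of chromosome X from 0.363 to 0.528. The mm9 set, the removal of chromosome 11, the higher-signal peaks with CpG-rich genes only and CpG-rich genes for pairs and X were chosen after seeing the data, as was the recount of the 58 occupied named genes (54 to 64). Of values for single lists, 165 kept their direction and their side of the threshold, 12 gained a call and 17 lost one, and 12 turned direction, with a cause that was not tested. Those 12 belong to lists that missed the main threshold: B cell genes stood at 27.5% in the conservative set, 27.5% without replicate 1 (45% without replicate 2, above other genes), 28.6% of CpG-rich genes, 25% in the mm9 set and 12.5% with the higher-signal peaks (adjusted exact p = 0.0407), below other genes in these 5 settings. With the higher-signal peaks and CpG-rich genes only, B cell genes stood at 28.6%, histone genes at 28.6% and mitochondrial DNA genes at 46.7%, each below other genes. Histone genes stood at 22.8% with the higher-signal peaks, 52.4% of CpG-rich genes and 12.7% in the mm9 set (adjusted exact p = 0.000441), again below other genes, and mitochondrial DNA genes at 60% of CpG-rich genes. Not run for lack of an mm10 genome were the motif results on the conservative set and on each replicate alone. Depth is unknown, so weak peaks cannot be weighed by reads.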

Other observations

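Some germline genes with no NRF1 peak held the NRF1 consensus. Genes of meiosis and germ cells are silent in most somatic cells, and 7 of the 35 with promoter sequence carried the consensus within 1000 bp of a TSS (20% against 5.77% of other genes, adjusted Fisher's exact p = 0.0145). These were Hormad1, Spo11, Stk31, Syce1, Taf7l, Tex15 and Tex19.1, chosen after their values were seen, and none was occupied. Since none of the 36 germline genes was occupied, this adds no test of the sites themselves. Of genes with the consensus in the other tissue lists, 0 of 2 T cell and myeloid, 0 of 1 B cell, 1 of 3 synapse and 1 of 2 olfactory receptor genes were occupied, and of those in oxidative phosphorylation 15 of 15, where the 14 with a CpG-rich promoter did not differ from other such genes with the consensus (81.8% occupied, adjusted Fisher's exact p = 0.613). DNA methylation and expression were not analysed here.

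The tests of weaker peaks and of CpG-rich promoters on chromosome X were chosen after the results were seen, and the signal test on chromosome X was written before.

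The weaker peaks seldom held the NRF1 site. Copies of GCGCATGCGC with up to 1 mismatch are argued against as the main cause, since 5.62% of the 5608 lower-signal mm9 peaks held one (interval 5.04 to 6.25). Partial sites and copies with more mismatches were not counted, so weaker copies of those kinds stay open. Noise spread evenly over the genome is argued against as the whole of the lower-signal mm9 peaks. Of these, 55.2% lay within 1000 bp of a TSS, against at most 2.84% in random placements of all mm9 peaks. On mm10, a different set, 32.6% of the 8774 lower-signal optimal peaks lay at promoters. Random placements gave at most 2.02% there, and relaxed peaks outside the set 4.22%. Noise that gathers at promoters was not tested by this, and noise as a part stays open. Of the 8774, 41.3% were among the top peaks of both replicates (99.4% of the higher-signal ones), with a replicate rho of 0.143. The split by signal narrows their range and puts them near the cut for top peaks, so neither value tells noise from weak binding. The CTCF site was 22.0 times as frequent at the summits of lower-signal mm9 peaks as in their flanks (interval 11.5 to 42.0). That interval counts the error of the 10 flank windows with the site. Of the 1121 weakest peaks, 3.75% held it. The site was also raised at the summits of higher-signal mm9 peaks (0.535% against 0.0713% of flanks), so it is not particular to the weaker ones. Pull-down of open regions held by other factors may account for part of the lower-signal peaks. The mm9 set has no control among its inputs, so such pull-down cannot be told from signal that arises without the antibody. NRF1 brought to such sites by another protein stays open and was not tested.

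Genes on chromosome X were occupied less often. A shortage of CpG-rich promoters is argued against as the whole cause, because the odds ratio among genes with one was 0.528 (interval 0.413 to 0.676). Occupied X genes with a CpG-rich promoter and the consensus had a lower signal than autosomal ones, by a median difference of -139.9 (388 over 19 genes against 528 over 841, permutation p = 0.00526), which is consistent with weaker signal at the same kind of site, as fewer copies of X would give. Pooled relaxed peaks outside the optimal set were sparse on X too, at 12.1 per Mb against a median of 103 over 20 chromosomes. Bins of X held a median of 0.0957 times the peaks of autosomal bins with a like number of genes (31 bins). This comparison was chosen after the results were seen. Low counts on X are therefore not confined to promoters with the consensus. Fewer active genes on X and a lower copy number stay open, and these counts do not tell them apart. Occupancy of these motif-bearing genes was 67.9% of 28 on X and 82.5% of 1020 on autosomes (Fisher's exact p = 0.0748).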
